A study of Mus musculus with 8 samples.

How the data were processed

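RNA was measured in 8 libraries of endothelial cells from mouse embryonic brain at E14.5, 4 from Flvcr2 heterozygous and 4 from Flvcr2 knockout embryos of the C57Bl6 strain. Per the labels, the Flvcr2 mutation makes cells express GFP, and cells positive for both GFP and CD31, a surface protein of endothelial cells, were sorted by flow cytometry. Each library came from 2000 to 5000 cells. Complementary DNA was made with the SMART-Seq v4 kit and libraries with the Nextera XT kit, per the labels' protocols. Single-end reads of 50 nucleotides were sequenced on a HiSeq4000, with over 40 M reads stated per sample. The labels do not say whether libraries of a group came from separate embryos, so p-values measure the spread between these libraries, part of which may be technical.

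The deposited table holds raw counts per gene symbol for the 8 libraries. The submitters' processing notes name TopHat2 version 0.7, Cufflinks version 2.2.1 and the genome build mm10. The program that made the counts, its strand setting and its treatment of reads that map to several genes are not given in the sources used here. Values of antisense or overlapping genes and of near-identical gene copies, such as the globins, are therefore uncertain. The table has 24421 rows, of which 6388 are 0 in every library, and no mitochondrially encoded gene, whose share was therefore not analysed here. Among the symbols, 27 had been turned into dates by a spreadsheet program; 21 of these were tested, and none is named. Flvcr2 is listed under its older symbol Mfsd7c, and 6 symbols of the gene lists were matched through synonyms in the RefSeq gene table. Coordinates come from that table, assembly GRCm38.p6, the same build as mm10; 99.6% of the tested genes were located in it.

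Counts were analysed in R 4.3.3. Genes were kept by edgeR's filterByExpr (edgeR 4.0.16; minimum count 10, minimum total 15), which left 13540 genes holding 99.9% of the counts. Library sizes were scaled with TMM factors. Differences between knockout and heterozygous libraries were tested with edgeR's quasi-likelihood F-test with robust dispersion and no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Expression levels are given in CPM with TMM-scaled library sizes, as mean ± SD over 4 libraries; log2 CPM used a prior count of 2. Total counts ran from 9.11 to 35.9 M per library.

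Before the data were examined, 37 gene lists were fixed, 26 for endothelial biology and 11 for other cell types, dissociation stress and embryo sex. Lists with at least 3 tested members were tested with limma's camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the 26 or the 11 lists, and again with an estimated correlation and with fry. The mean log2 CPM of a list in each library was compared between genotypes with an exact two-sided permutation test over the 70 arrangements, whose smallest p is 0.0286. Genes near Flvcr2 were compared with all others by a two-sided Fisher's exact test. Named genes were chosen by a rule fixed at the same time. It takes Flvcr2 first. It then takes the 12 largest increases and the 12 largest decreases among called genes whose groups did not overlap and whose higher group averaged at least 5 CPM, leaving out Gm and Rik names. From each list it takes up to 4 called members by smallest p, or the 2 most abundant where none was called, and it adds the X-inactivation and Y-linked genes. Genes outside the rule are marked as chosen after their values were seen.

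The test was checked on simulated counts for the comparison of knockout with heterozygous libraries. Over 13540 genes, 39% of 100 genes changed by 2-fold and 68% of 100 genes changed by 4-fold were recovered, and 7 of the 114 calls were false. Of 20 unchanged lists, 0 were called. The simulated genes varied independently of each other, whereas the estimated correlation within the real endothelial lists reached 0.645. The simulation therefore does not check the camera calls of lists whose genes vary together. Libraries within a group differed by more than sampling noise in every pair (chi-square per degree of freedom at least 27.6), so none was counted as a library deposited a second time. This does not show that the libraries came from separate embryos or separate RNA.

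Alternatives were other scalings, other low-count filters, DESeq2 1.42.0, limma voom with and without sample weights, a non-robust dispersion, the replicate number as a block, a surrogate variable from sva 3.50.0, a sex index, other thresholds, and leaving out each library in turn. Further alternatives were chosen after the data were seen. They left out heterozygous 1 with knockout 2, or heterozygous 2 with knockout 1, or used a neuronal score (mean of the neuron and radial glia lists) or an other-cell score (mean of the neuron, radial glia, pericyte, microglia and erythroid list scores) as a covariate. Figures were drawn with matplotlib 3.10.9.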

Results

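Gene expression was measured by RNA sequencing in endothelial cells sorted from the brains of mouse embryos at E14.5 (embryonic day). The comparison asks how the transcriptome of brain endothelial cells differs when Flvcr2, a gene for a membrane transporter, is lost. Of the 8 libraries, 4 came from Flvcr2 heterozygous and 4 from Flvcr2 knockout embryos. Heterozygous libraries 1 to 4 held 9.56, 9.11, 22.6 and 18.0 M counts, and knockout libraries 1 to 4 held 21.0, 12.1, 17.9 and 35.9 M. The mean total did not differ between genotypes beyond the spread of libraries (14.8 ± 6.62 against 21.7 ± 10.1 M, SD, n = 4 each; exact permutation test, p = 0.314).

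Flvcr2 transcripts were counted in all 8 libraries. The gene (Entrez 217721) lies on chromosome 12 from 85746539 to 85813586 of GRCm38. Heterozygous libraries 1 to 4 had 276, 444, 578 and 409 CPM, and knockout libraries 1 to 4 had 393, 227, 260 and 326 CPM. The means were 427 ± 124 and 301 ± 73.6 CPM (SD, n = 4 each), a log2 fold change of -0.50 ± 0.24 (SE) that did not pass the test (edgeR adjusted p = 0.209). The 2 genotypes overlapped. Which part of the gene the mutation removes is not given in the sources used here, and reads from a mutant transcript are counted under the same symbol, so this value does not check the genotype labels.

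The first principal component of log2 CPM held 38.2% of the variance and separated the genotypes, with scores of -55.0 ± 26.9 in heterozygous and 55.0 ± 31.2 in knockout libraries (exact permutation test, p = 0.0286, the smallest this design allows; adjusted p = 0.114 over the library measures). Heterozygous 1 (-90.2) and knockout 2 (100.2) lay at its ends. The other-cell score also separated the genotypes, at 3.80 to 4.71 in heterozygous and 1.55 to 3.06 in knockout libraries. Within heterozygous libraries this score fell along the component. Within knockout libraries it did so except between knockout 4 and knockout 2 (1.55 and 1.61). Genotype and transcripts of other cell types therefore cannot be told apart on this component. Xist, the RNA that silences an X chromosome in female cells, was at 0 counts in heterozygous 2 and at 1 count in knockout 1, while both had transcripts of the Y-linked gene Ddx3y (331 and 914 counts). Each genotype thus had 1 library of this kind, and the other 6 had between 229 and 1135 counts of Xist. Heterozygous 3 and 4 also had 28 and 56 counts of Ddx3y.

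**Figure D1:**
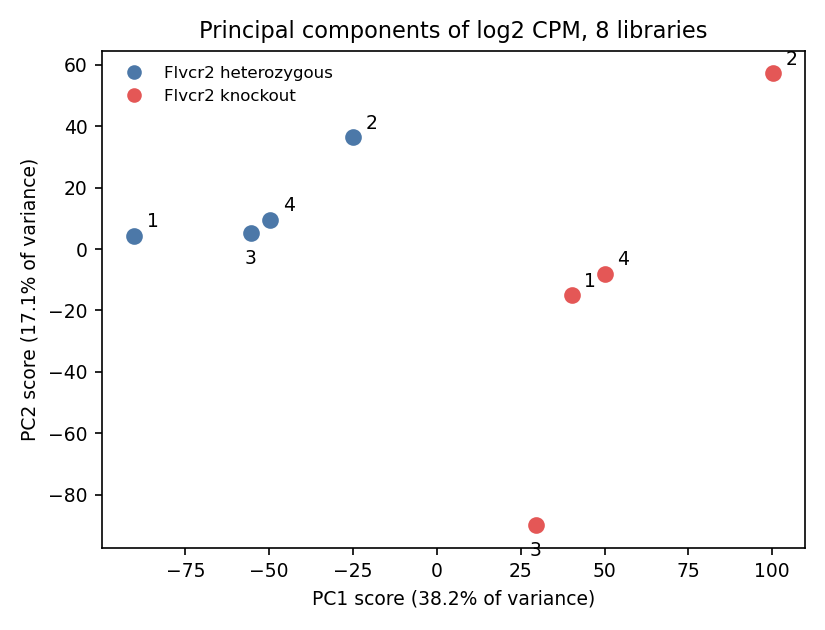
Scores of the 8 libraries on the first (x axis, 38.2% of variance) and second (y axis, 17.1%) principal components of log2 CPM, numbered by replicate and coloured by genotype. All 4 heterozygous libraries have negative and all 4 knockout libraries positive scores on the first component.

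In knockout cells 749 genes were higher and 544 lower than in heterozygous cells, out of 13540 tested (edgeR quasi-likelihood test, adjusted p under 0.05). Of these 1293 genes, 367 rose and 426 fell by at least 2-fold. The largest rises included Slc7a3, a transporter of cationic amino acids, at 0.410 ± 0.764 CPM in heterozygous and 43.1 ± 33.8 CPM in knockout libraries (log2 fold change 6.52 ± 1.03, SE). Its heterozygous libraries 1 to 4 were at 0, 0, 0.0854 and 1.55 CPM, and the log2 fold change ran from 5.92 to 9.71 over the 8 fits that left out 1 library. Angpt2, the angiopoietin that antagonises the Tie2 receptor, rose 18.6-fold from 34.9 ± 13.7 to 651 ± 351 CPM (edgeR adjusted p = 8.45e-04). The potassium channel subunit Kcne3 rose 14.2-fold, from 16.6 ± 5.78 to 239 ± 51.1 CPM (edgeR adjusted p = 1.17e-04). The cytosolic DNA sensor Aim2 rose 17.3-fold, the hyaluronan link protein gene Hapln1 19.2-fold and Clca2 15.8-fold. The KDEL receptor gene Kdelr3 rose by 3.85 on the log2 scale. Svopl, Eda2r, Inhba, Trib3 and Phlda3 completed the 12 largest rises, with log2 fold changes of 5.57, 4.70, 4.10, 4.06 and 3.86.

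The largest falls included the embryonic globin genes Hbb-y and Hba-x, which fell 20.9-fold and 21.6-fold, from 346 ± 174 to 16.4 ± 6.15 CPM and from 63.2 ± 33.8 to 2.76 ± 3.17 CPM. Lower still in level were Lrrc4, Plce1 and Grb7, at 6.16, 5.30 and 9.52 CPM in heterozygous and 0.0688, 0.0928 and 0.198 CPM in knockout libraries. Tmem169, Elmod1, Oprl1, Aff3, Chl1 and Lhfpl4 fell by 4.38, 4.23, 4.22, 4.12, 4.08 and 4.06 on the log2 scale. Of the 24 genes that the rule took for their size of change, Inhba, Hba-x, Tmem169, Elmod1 and Aff3 lost their call in at least 1 of the 8 fits that left out 1 library, while the other 19 were called in all 8. The groups did not overlap for 17.6% of all tested genes, against 2.86% by chance.

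The count of called genes differed between sets of libraries and between models. It was 579 without knockout 1, 625 without knockout 4, 787 without heterozygous 1 and 790 without heterozygous 3, 300 without both libraries that had Y-linked transcripts and almost no Xist, 114 with the neuronal score as a covariate and 0 with the other-cell score (1174 at an unadjusted p under 0.05 in edgeR; DESeq2, run without a covariate, called 2229). The median absolute log2 fold change of the 1293 genes was 1.18 (median SE 0.234), 1.03 (0.328) with the neuronal score and 0.91 (0.524) with the other-cell score, so errors widened more than folds shrank. With library size alone as the scaling, 42.6% of the called genes were higher in knockout, against 57.9% with TMM, and the median log2 fold change of all genes moved by -0.12. The TMM factors averaged 1.04 ± 0.04 in heterozygous and 0.96 ± 0.02 in knockout libraries (SD; exact permutation test, p = 0.0286, adjusted 0.114). The scaling thus differed with genotype, and the balance of higher and lower genes depends on it.

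**Figure D2:**
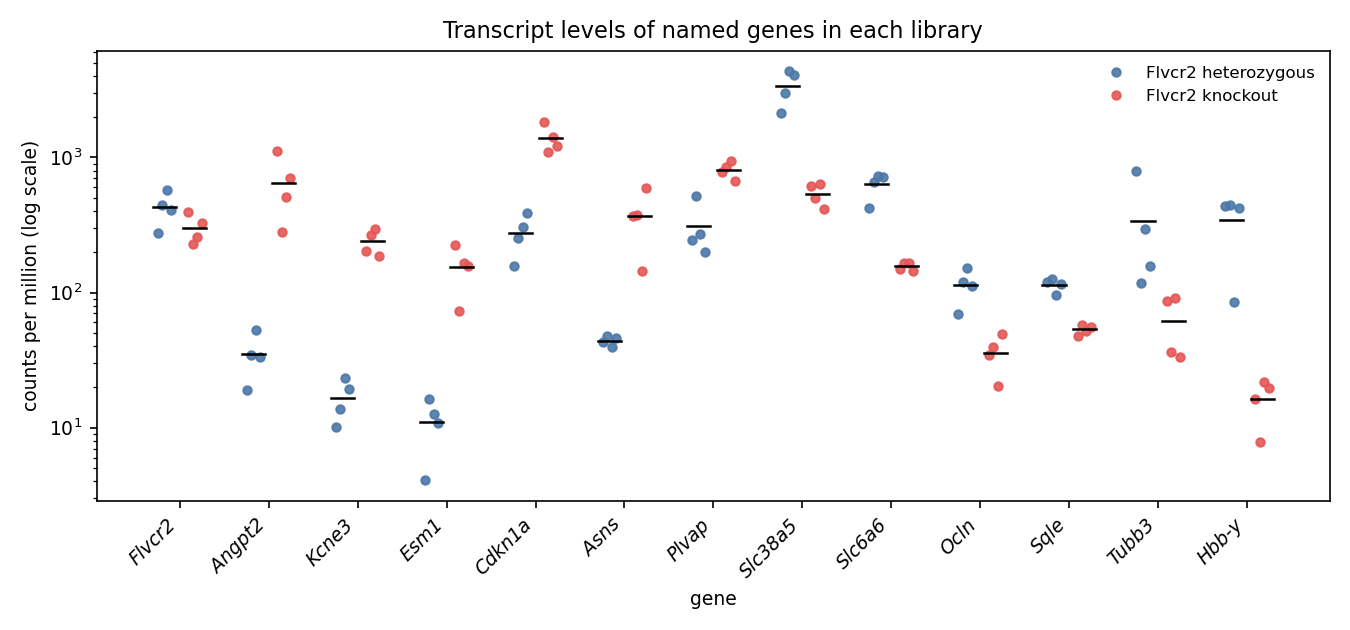
CPM (y axis, log scale) of 13 named genes (x axis) in each library, coloured by genotype, with black lines at the means. Flvcr2 overlaps between genotypes, while Angpt2 averages 34.9 CPM in heterozygous and 651 CPM in knockout libraries.

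Transcripts of neurons, radial glia, pericytes and embryonic red cells were lower in knockout libraries. Of 20 tested neuron genes, 8 fell and 0 rose, with a median log2 fold change of -2.37 (17 fell when adjusted over the list alone). Tubb3, the neuronal tubulin, fell 5.47-fold from 339 ± 309 to 61.9 ± 31.4 CPM; Dcx, Neurod2 and Elavl3 fell 6.27-fold, 6.72-fold and 5.86-fold. Heterozygous 1 had 789 CPM of Tubb3, against 118, 293 and 156 CPM in heterozygous 2 to 4. The smallest log2 falls over the 8 fits that left out 1 library were 1.61, 1.81, 2.14 and 1.69 for these 4 genes. Left-out libraries ended these calls in 3 to 5 of 8 fits for Elavl3, Neurod2 and Tubb3 and in 2 for Dcx (without knockout 1 or 4). The mean log2 CPM of the neuron list was 5.52, 2.81, 4.38 and 2.92 in heterozygous and 2.27, 0.23, 2.93 and 1.09 in knockout libraries 1 to 4. Of 13 radial glia genes 3 fell (Pax6, Slc1a3 and Lhx2; 3 adjusted over the list alone), and of 13 pericyte and smooth muscle genes 2 fell (Cspg4 and Des; 3 adjusted over the list alone). Of 16 microglia and macrophage genes Ctss fell (11 adjusted over the list alone), and of 5 tested erythroid genes Hbb-y and Hba-x fell (3 adjusted over the list alone). The calls of Slc1a3, Lhx2, Cspg4, Des and Ctss each held in at most 3 of the 8 fits that left out 1 library. The adult globin genes are listed at 0 in every library.

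By camera these 5 lists and the fibroblast list were lower in knockout (adjusted p = 1.26e-06 for neurons, 4.11e-04 for radial glia, 3.50e-04 for pericytes, 1.20e-04 for microglia, 0.0210 for erythroid cells and 0.0246 for fibroblasts and meninges). None of these calls held with an estimated correlation, where adjusted p-values were 0.491 for 5 of them and 0.422 for erythroid cells. Exact permutation p of the list means was 0.0286 for pericytes and erythroid cells, 0.0571 for microglia, 0.0857 for neurons and radial glia and 0.171 for fibroblasts (adjusted 0.157 to 0.269). The fibroblast call was also lost with library size alone as the scaling (adjusted p = 0.0630), without heterozygous 1 or 3 or knockout 1, 2 or 4, and without heterozygous 1 and knockout 2 (adjusted p = 0.146; 6.24e-05 to 0.916 over all alternatives). Of the fibroblast genes 0 of 12 were called (0 adjusted over the list alone); Col3a1 was at 108 ± 38.1 and 82.6 ± 109 CPM, and Foxc1 at 75.7 ± 15.2 and 73.9 ± 12.3 CPM. Lists of platelets (0 of 7 called), choroid plexus (0 of 7) and oligodendrocyte precursors (0 of 6, 1 adjusted over the list alone) did not pass camera (adjusted p = 0.939, 0.763 and 0.0585), though the precursor list did with the replicate number as a block (0.00947) and without heterozygous 2, knockout 1 or both (0.0108, 0.0272 and 0.00109). The platelet genes Pf4 and Itga2b had log2 fold changes of 0.23 and 0.95 and were not called. Ttr of choroid plexus was at 2301 ± 4303 and 524 ± 516 CPM, and Enpp2 at 394 ± 101 and 512 ± 71.9 CPM. The precursor genes Cspg5 and Olig1 were at 11.3 ± 6.72 and 3.06 ± 1.41 CPM, and at 6.81 ± 5.34 and 2.55 ± 2.62 CPM. The X-inactivation and Y-linked list had 0 of 3 tested members called (camera adjusted p = 0.763), with a median log2 fold change of 0.27 and a mean of -0.22.

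**Figure D3:**
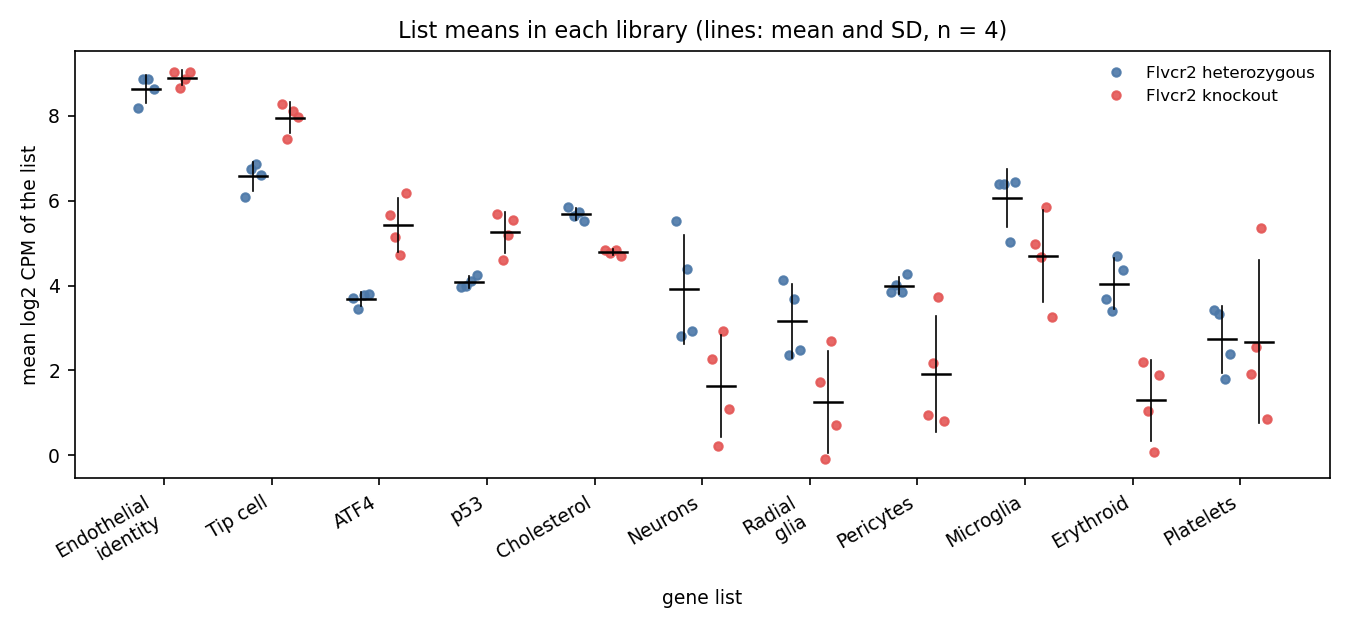
Mean log2 CPM of 11 gene lists (x axis) in each library, coloured by genotype, with lines at the mean and SD of 4 libraries. The cholesterol list averages 5.69 in heterozygous and 4.79 in knockout libraries, and the neuron list 3.91 and 1.63.

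Genes of endothelial tip cells, the leading cells of growing vessels, were higher in knockout. Of 24 tested genes 14 rose and 0 fell (17 rose when adjusted over the list alone), with a median log2 fold change of 1.26 (camera adjusted p = 4.19e-11; adjusted p = 0.398 with an estimated correlation). Beside Kcne3 and Angpt2, Esm1 rose 14.1-fold from 11.0 ± 5.14 to 155 ± 62.2 CPM, and Plaur, the urokinase receptor gene, 4.05-fold. The list mean was 6.57 ± 0.34 in heterozygous and 7.96 ± 0.36 in knockout libraries (SD, n = 4 each; exact permutation test, p = 0.0286, adjusted over 26 lists 0.106). These 4 genes were called in all 8 fits that left out 1 library. The neuron list mean fell between the same libraries, from 3.91 ± 1.29 to 1.63 ± 1.21.

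Of 24 basement membrane and matrix genes 10 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 fold change of 0.61 (camera adjusted p = 2.08e-05; adjusted p = 0.639 with an estimated correlation). The list mean did not pass the exact permutation test (p = 0.0857, adjusted 0.223), and 6 genes rose with library size alone as the scaling and 4 with the replicate number as a block. The laminin chain genes Lamb1 and Lamc1 rose 2.38-fold and 1.92-fold, the integrin gene Itga6 1.87-fold, and P4hb, a subunit of the collagen prolyl hydroxylase, 1.92-fold. Lamb1 lost its call without knockout 4. Of 10 genes for VEGF receptors and ligands 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.122). Plxnd1 rose 2.18-fold, Nrp1 1.73-fold and Pgf 3.31-fold, and Vegfb fell 2.22-fold. Of these, Plxnd1 alone was called in all 8 fits that left out 1 library. Of 20 TGF-beta and BMP genes 4 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0930), namely Ctgf, Tgfbi, Cyr61 and Tgfb1, by 3.06-fold, 2.60-fold, 2.41-fold and 1.76-fold. The calls of Cyr61 and Tgfb1 held in 5 and 2 of those 8 fits. The pericyte list mean differed by -2.08 between the same groups of libraries.

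Targets of the stress transcription factor ATF4 were higher in knockout. Of 24 tested genes 14 rose and 0 fell (18 rose when adjusted over the list alone), with a median log2 fold change of 1.55 (camera adjusted p = 7.45e-10; adjusted p = 0.398 with an estimated correlation). Asns, the asparagine synthetase gene, rose 8.37-fold from 44.0 ± 3.49 to 368 ± 182 CPM. Mthfd2, an enzyme gene of mitochondrial folate metabolism, rose 9.95-fold, the pseudokinase gene Trib3 16.7-fold and the translation repressor gene Eif4ebp1 5.26-fold. Of 18 genes for chaperones of the endoplasmic reticulum and the unfolded protein response 4 rose and 0 fell (5 adjusted over the list alone; median log2 fold change 0.38; camera adjusted p = 8.71e-05; adjusted p = 0.533 with an estimated correlation; exact permutation p of the list mean 0.0286, adjusted 0.106). These were Herpud1 (2.31-fold), Creld2 (1.67-fold), Xbp1 (1.61-fold) and Syvn1 (1.75-fold), of which Syvn1 was called in 2 of the 8 fits that left out 1 library.

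Targets of p53 were also higher, with 7 of 18 rising and 0 falling (9 adjusted over the list alone) and a median log2 fold change of 0.88 (camera adjusted p = 3.62e-06; adjusted p = 0.398 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose 4.99-fold from 277 ± 97.0 to 1385 ± 324 CPM, Zmat3 3.33-fold and Eda2r, a receptor gene of the TNF family, 25.9-fold. Phlda3, a repressor gene of the kinase Akt, rose from 9.93 ± 4.42 to 143 ± 72.0 CPM. List means of ATF4 targets and p53 targets separated the genotypes, at 3.68 ± 0.16 against 5.43 ± 0.64 and at 4.08 ± 0.14 against 5.26 ± 0.49 (exact permutation test, p = 0.0286 each, adjusted 0.106). The neuron list mean differed by -2.28 between the same groups of libraries.

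Genes of cholesterol synthesis and uptake were lower in knockout. Of 23 tested genes 12 fell and 0 rose (14 fell when adjusted over the list alone), with a median log2 fold change of -0.80 (camera adjusted p = 5.25e-09; adjusted p = 0.0553 with an estimated correlation). Sqle, the squalene epoxidase gene, fell 2.14-fold from 114 ± 12.7 to 53.4 ± 4.18 CPM (edgeR adjusted p = 0.00196). Insig1 fell 2.55-fold, Fdft1 2.59-fold and Fdps 2.14-fold, and all 4 genes were called in each of the 8 fits that left out 1 library. The list mean was 5.69 ± 0.14 in heterozygous and 4.79 ± 0.07 in knockout libraries (exact permutation test, p = 0.0286, adjusted 0.106). The list means of neurons and of microglia, which were lower in the same libraries, differed by -2.28 and -1.37.

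**Figure D4:**
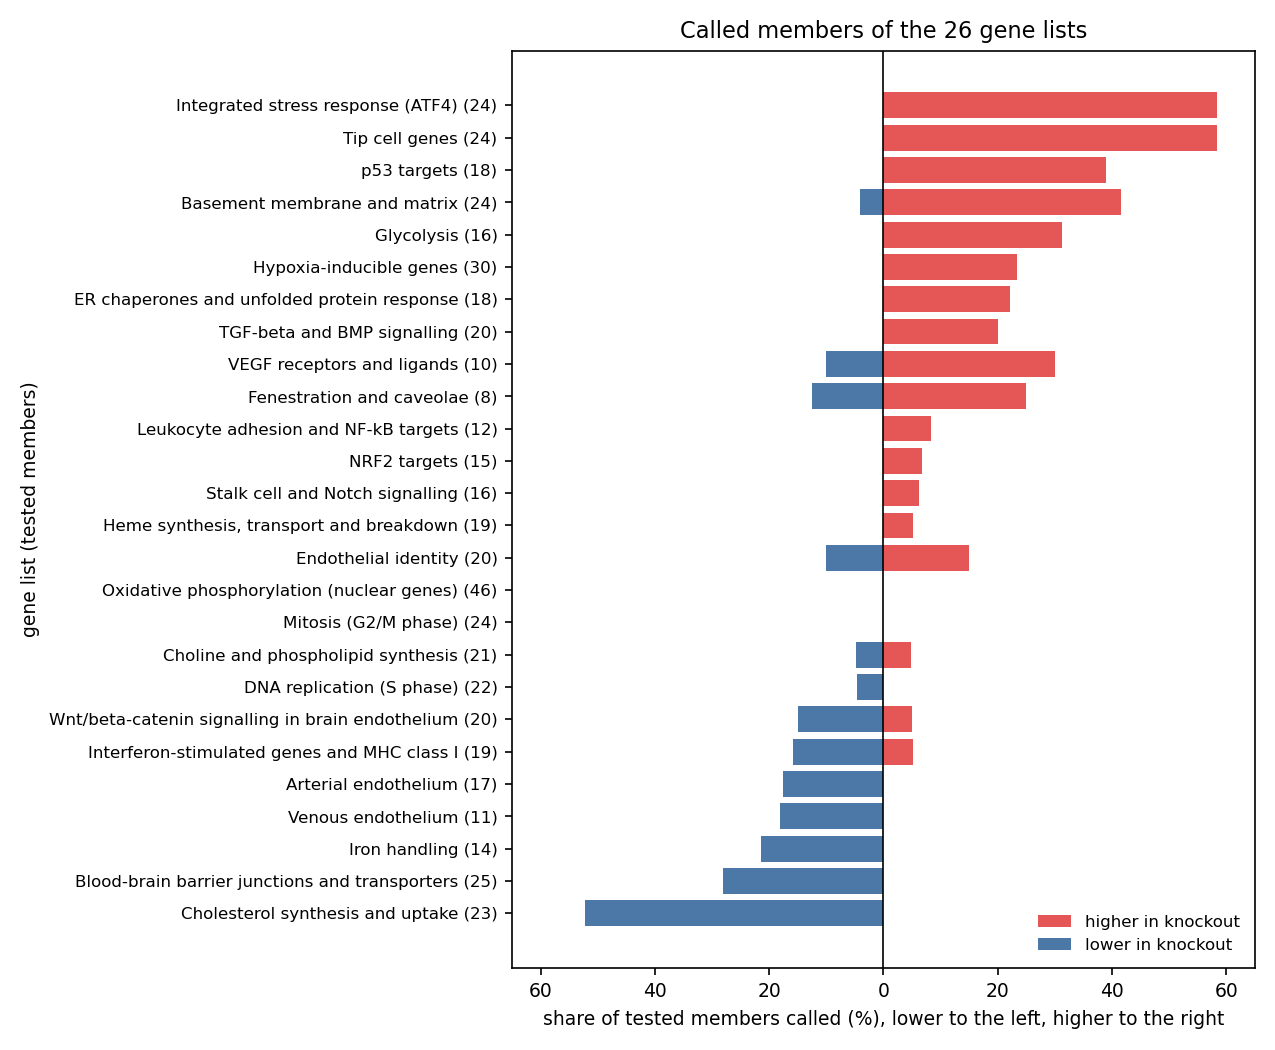
Share of tested members (x axis, %) called lower (left) or higher (right) in knockout for the 26 endothelial gene lists (y axis, tested members in brackets). The ATF4 and tip cell lists reach 58.3% higher, and the cholesterol list 52.2% lower.

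Several transporters and junction genes of the blood-brain barrier were lower in knockout. Of 25 tested genes 7 fell and 0 rose (8 fell when adjusted over the list alone), with a median log2 fold change of -0.27 (camera adjusted p = 0.0176; adjusted p = 0.771 with an estimated correlation). The mean of this list did not pass the exact permutation test (p = 0.114, adjusted 0.248). The amino acid transporter gene Slc38a5 fell 6.25-fold from 3377 ± 1019 to 540 ± 103 CPM, and the taurine transporter gene Slc6a6 4.03-fold from 631 ± 142 to 157 ± 11.3 CPM. The tight junction genes Ocln and Lsr fell 3.15-fold and 1.77-fold. Lsr lost its call without heterozygous 2 or knockout 1. Cldn5, Slc2a1 and Mfsd2a, chosen after their values were seen, had log2 fold changes of -0.45, -0.27 and 0.07 and were not called (edgeR adjusted p = 0.140, 0.424 and 0.901). The list's camera call was lost without heterozygous 2, 3 or 4 or knockout 2, and over the 8 fits that left out 1 library its adjusted p ran from 2.76e-05 to 0.106. It was also lost with the replicate number as a block (adjusted p = 0.0741). Neuron, pericyte and erythroid list means differed by -2.28, -2.08 and -2.75 between the same libraries.

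Of 20 Wnt/beta-catenin genes 3 fell and 1 rose (5 and 1 adjusted over the list alone; median log2 fold change -0.50; camera adjusted p = 0.0368; adjusted p = 0.743 with an estimated correlation). The feedback inhibitor genes Nkd1 and Notum fell 2.38-fold and 6.02-fold and Tnfrsf19 1.82-fold, while the receptor gene Fzd4 rose 2.32-fold; Notum and Fzd4 were called in 3 and 4 of the 8 fits that left out 1 library. Of 11 venous genes Slc38a5 and Nr2f2 fell (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0442; adjusted p = 0.560 with an estimated correlation), and Nr2f2, a transcription factor gene of veins, fell 1.88-fold but was called in 1 of the 8 fits. Of 17 arterial genes 3 fell (4 adjusted over the list alone; camera adjusted p = 0.201), the connexin genes Gja5 (2.69-fold) and Gja4 (1.72-fold) and Stmn2, a gene also known from neurons (3.69-fold). The calls of Gja4 and Stmn2 each held in 3 of those 8 fits. The Wnt camera call was lost without heterozygous 2, 3 or 4 or knockout 2 or 3 (adjusted p from 6.75e-04 to 0.131 over the 8 fits), and the venous call without heterozygous 2, 3 or 4 or knockout 1 or 3 (from 0.00825 to 0.104). Both were also lost with the replicate number as a block (adjusted p = 0.0950 and 0.0806) and without heterozygous 2 and knockout 1 (0.0719 and 0.153), and the venous call with the sex index as a covariate (0.0507). For the list means the exact permutation p was 0.0857 (Wnt, adjusted 0.223) and 0.0286 (venous, adjusted 0.106). The neuron and pericyte list means differed by -2.28 and -2.08 between these libraries.

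Plvap, the diaphragm protein of fenestrated vessels, rose 2.63-fold from 308 ± 144 to 810 ± 112 CPM. In its list of 8 genes Cavin3 rose 1.77-fold, a call held in 3 of the 8 fits that left out 1 library, and Cavin2 fell 2.51-fold (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.672). Of 20 endothelial identity genes 3 rose and 2 fell (8 and 2 adjusted over the list alone; median log2 fold change 0.08; camera adjusted p = 0.0930). The identity list passed camera as higher with no filter (adjusted p = 0.0445), with the sex index as a covariate (0.0357), and without heterozygous 2, knockout 2 or heterozygous 2 and knockout 1 (0.0339, 0.0341 and 0.0467; 0.0339 to 0.929 over all alternatives). Emcn and Mmrn2 rose 2.28-fold and 2.67-fold and Cd34 rose from 1725 ± 319 to 3450 ± 540 CPM. Sox18 fell 1.74-fold, a call held in 2 of the 8 fits that left out 1 library. The identity list mean was 8.64 ± 0.32 in heterozygous and 8.90 ± 0.18 in knockout libraries (exact permutation test, p = 0.229). Of 16 stalk cell and Notch genes Mfng rose 1.47-fold (0 called adjusted over the list alone; camera adjusted p = 0.869); its call held in 1 of those 8 fits. In the same libraries the erythroid list mean was 4.05 ± 0.60 and 1.30 ± 0.95.

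Of 30 hypoxia-inducible genes 7 rose and 0 fell (10 rose adjusted over the list alone; median log2 fold change 0.29; camera adjusted p = 0.00269; adjusted p = 0.534 with an estimated correlation). Adm, the adrenomedullin gene, rose 4.04-fold from 108 ± 41.7 to 438 ± 107 CPM, Egln3 5.90-fold, Ero1l 2.70-fold and Ldha 1.69-fold. The exact permutation p of the hypoxia list mean was 0.0286 (adjusted 0.106) and of the glycolysis list mean 0.143 (adjusted 0.248). With each of the 3 other scalings 3 glycolysis genes rose. Vegfa, chosen after its values were seen, was at 4.40 and 4.68 CPM and was not called. Of 16 glycolysis genes 5 rose and 0 fell (10 rose and 1 fell adjusted over the list alone; median log2 fold change 0.41; camera adjusted p = 0.00111; adjusted p = 0.398 with an estimated correlation). The lactate transporter gene Slc16a3 rose 4.24-fold, Gpi1 1.69-fold and Gapdh 1.41-fold; Gpi1 and Gapdh were called in 6 and 1 of the 8 fits that left out 1 library. Of 46 genes of oxidative phosphorylation 0 were called (0 adjusted over the list alone; camera adjusted p = 0.199), with Atp5b at 2111 ± 87.1 and 2626 ± 239 CPM and Atp5a1 at 1087 ± 27.1 and 1296 ± 150 CPM. The list means of neurons, pericytes and erythroid cells differed by -2.28, -2.08 and -2.75 between the same libraries.

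The heme, iron, choline and NRF2 lists did not pass camera, except the iron list with a filter at a mean of 5 CPM (adjusted p = 0.0413, and up to 0.575 over the other alternatives). Of 19 heme genes Cpox, an enzyme gene of heme synthesis, rose 2.56-fold from 23.6 ± 5.99 to 60.2 ± 11.5 CPM and 0 fell (1 adjusted over the list alone; camera adjusted p = 0.672). Of 14 iron genes 3 fell (4 adjusted over the list alone; camera adjusted p = 0.199), the transferrin receptor gene Tfrc 2.55-fold, the ferritin gene Fth1 1.71-fold and Steap3 2.31-fold; each call held in 1 of the 8 fits that left out 1 library. Of 21 choline and phospholipid genes Ptdss2 rose 1.48-fold and Slc44a5 fell 8.12-fold (1 and 1 adjusted over the list alone; camera adjusted p = 0.512), calls held in 3 and 1 of those fits; the list's median log2 fold change was 0.12 and its mean -0.18. Of 15 NRF2 targets Osgin1 rose 2.57-fold (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.600), a call held in 2 of those fits. Erythroid and microglia list means differed by -2.75 and -1.37 between the same libraries.

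Of 22 DNA replication genes Mcm7 fell 2.09-fold and 0 rose (3 fell adjusted over the list alone; median log2 fold change -0.22; camera adjusted p = 0.0368; adjusted p = 0.771 with an estimated correlation). The list call was lost without heterozygous 2 or 3 or knockout 1 or 3 (camera adjusted p from 1.12e-04 to 0.321 over the 8 fits that left out 1 library), with the replicate number as a block (0.0862) and without heterozygous 2 and knockout 1 (0.389). Its mean did not pass the exact permutation test (p = 0.229, adjusted 0.297), and the neuron list mean differed by -2.28 between the same libraries. Of 24 mitosis genes 0 were called (0 adjusted over the list alone; camera adjusted p = 0.294), and Cdk1 and Ccnb1 were at 152 ± 22.7 and 161 ± 56.0 CPM and at 127 ± 15.7 and 143 ± 46.0 CPM. Of 12 leukocyte adhesion and NF-kB genes Icam1 rose 1.96-fold (1 adjusted over the list alone; camera adjusted p = 0.298). Of 19 interferon and MHC class I genes Oasl2, Rsad2 and Irf7 fell 7.04-fold, 7.79-fold and 9.09-fold and Tap1 rose 5.32-fold (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.199); each was called in at most 4 of the 8 fits that left out 1 library, and the 3 falls were lost without heterozygous 4. The smallest log2 falls over these fits were 2.03, 1.55 and 1.52. Of 19 immediate-early and heat-shock genes Atf3 rose 2.02-fold and Fos fell 2.87-fold (1 and 1 adjusted over the list alone; camera adjusted p = 0.763); the Fos call held in 1 of those fits, and the list's median log2 fold change was 0.14 and its mean -0.07.

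Of 103 called genes that the rule took, all 103 kept their direction and 60 their call in each of the 8 fits that left out 1 library. The call held for 46 of them without heterozygous 2 and knockout 1, for 23 with the neuronal score as a covariate and for 0 with the other-cell score, where 9 turned direction. In all, 12 of the 26 endothelial lists passed camera with the preset correlation, 0 with an estimated correlation and 8 by fry for a shift in a single direction. By fry for changes in either direction 23 passed, the heme, iron, choline and NRF2 lists among them. Some lists share genes, such as Slc38a5 (barrier and venous), Adm (tip cell and hypoxia) and Ldha (hypoxia and glycolysis). Their calls are therefore not separate results. The test found no difference in the share of called genes near Flvcr2. Within 5 Mb of the gene 6 of 76 tested genes were called (7.89%), against 9.56% elsewhere (odds ratio 0.811, 95% interval 0.287 to 1.86; two-sided Fisher's exact test, p = 0.844). The odds ratio was above 1 in a window of 1 Mb (1.35; Fisher's exact test, p = 0.496). The called genes included Ttc9, Jdp2, Entpd5, Fos and Pgf on chromosome 12. Of these, Ttc9, Jdp2 and Entpd5, named here after their values were seen, rose by 3.02, 1.55 and 1.25 on the log2 scale.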

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

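The search for libraries far from their group was planned, while the tests of explanations in this part were chosen after the results were seen. A library is listed where its gap to the nearest of the other 3 libraries of its genotype takes up more of the group's range than Dixon's test allows at 95%. For single genes the gap and range were taken on log2 CPM, while the values are printed in CPM. This held in 20 of 318 groups of values, where chance alone gives about 15.9 (5%).

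Among mean log2 CPM of gene lists, heterozygous 1 had 6.79 for venous genes (others 7.21 to 7.28), heterozygous 3 had 6.05 for DNA replication genes (5.83 to 5.86) and 5.04 for microglia genes (6.39 to 6.44). Knockout 4 had 3.35 for interferon genes (3.68 to 3.72), knockout 3 had 4.42 for fibroblast genes (1.78 to 2.10) and knockout 1 had 2.23 for X-inactivation and Y-linked genes (-0.33 to 0.01). In heterozygous 1, Sox18 was at 342 CPM (others 608 to 650) and Tnfrsf19 at 123 CPM (186 to 195). In heterozygous 2, Aff3 was at 1.17 CPM (7.09 to 7.88) and Xist at 0 CPM (18.9 to 47.8). In heterozygous 3, Hbb-y was at 84.9 CPM (420 to 445) and Ctss at 56.5 CPM (155 to 188). In heterozygous 4, Rsad2 was at 28.1 CPM (3.40 to 3.99). In knockout 1, Clca2 was at 52.8 CPM (31.6 to 33.9), Xist at 0.0511 CPM (32.7 to 40.8) and Ddx3y at 46.7 CPM (0 to 0.173). In knockout 2, Svopl was at 14.46 CPM (9.11 to 9.40) and Tap1 at 10.5 CPM (53.3 to 70.2). In knockout 3, Notum was at 0.456 CPM (3.22 to 3.81) and Cavin3 at 282 CPM (455 to 500).

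Heterozygous 3 and knockout 3 stand apart in markers of other cell types, which were lower in knockout libraries, with the neuron list falling from 3.91 to 1.63 in mean log2 CPM and its most abundant member Tubb3 from 339 to 61.9 CPM. The sort for GFP and CD31 should remove neurons, so carry-over of neural cells or their RNA that varies between sorts may account for part of this. The GFP used for the sort comes from the Flvcr2 mutation itself, so sorting and genotype are linked by design, and this was not tested. Within genotypes the neuron markers moved together, with a mean residual correlation of 0.761. This lay above all 10000 random lists matched on expression (95th percentile 0.0765) and above the highest endothelial list (0.645). However, 22 of the 26 endothelial lists also lay above that percentile, so carry-over cannot be told apart from other shared variation. A lower endothelial share in heterozygous libraries would raise all 9 lists of other cell types alike, but whether they moved apart cannot be told, since the smallest exact permutation p of a list against the mean of the others was 0.171 (platelets, apart by 1.70, two-sided), with 4 libraries per genotype. A change of the sorted cells or of their neighbours with genotype stays open and was not tested.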

How the results depend on the processing

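The settings that left out a pair of libraries or used the neuronal or other-cell score were chosen after seeing the data, as were the secretory, GIMAP and 2 synthetase lists; the other settings were planned. All 1293 called genes kept their direction where they were tested, except with the other-cell score, where 1191 did. Flvcr2 stayed uncalled in every setting, with a log2 fold change from -0.66 to -0.32 over the fits that left out 1 library, and 8 to 14 of 26 lists passed camera over these fits. On simulated counts 39% of 2-fold changes were recovered. How calls depend on depth was not tested. The number of called genes was 2229 with DESeq2 (1119 lower), 2266 with weighted voom (1186 higher, 1080 lower), 671 with a surrogate variable (413 higher, 258 lower), and 433 were higher with the replicate block; the cause was not tested. By construction it was 2081 at an adjusted p of 0.10 (1125 higher, 956 lower) and 241 when testing for a fold beyond 1.5 (142 higher, 99 lower). It was 842 without heterozygous 1 and knockout 2 (307 lower), 300 without heterozygous 2 and knockout 1 (180 higher, 120 lower), and 579 to 1347 without 1 library (371 to 715 higher, 208 to 640 lower); the cause was not tested. With the neuronal score it was 114 (76 higher, 38 lower), and with the other-cell score 0 (0 higher, 0 lower; 1174 at an unadjusted p under 0.05 in edgeR). The median absolute log2 fold change of the called genes was 1.18 (median SE 0.234), 1.03 (0.328) with the neuronal and 0.91 (0.524) with the other-cell score. Both scores track genotype (variance inflation 2.11 and 5.31), so the calls ended mainly through wider errors. With the replicate block 8 of the 12 lists kept their camera call, and the blood-brain barrier, Wnt, venous and DNA replication lists lost it (adjusted p = 0.0741, 0.0950, 0.0806 and 0.0862). With an estimated correlation 0 of the 26 endothelial lists and 0 of the 11 other fixed lists passed camera. The secretory list did (camera adjusted p = 0.0386), but it was adjusted only over the 4 lists chosen after seeing the data. The cholesterol list had a smaller camera p before adjustment (0.00213) and 0.0553 after adjustment over 26 lists. The secretory list is thus not shown to be stronger than the fixed lists. Within 1 Mb of Flvcr2 the odds ratio was 1.35, and the cause of these changes was not tested. The following log2 fold changes turned direction, and the cause was not tested. For lists the direction is camera's, and the value given is the median log2 fold change, which may keep its sign. With library size alone Cdk1 was at -0.0301. With a mean of at least 5 CPM the stalk list was at 0.0460 and the platelet list at 0.39. With voom Pf4 was at -0.66, Xist at -0.36 and Ddx3y at -2.09. With weighted voom Cdk1 was at -0.10, Pf4 at -1.28, Ttr at 0.99, Xist at -0.91 and Ddx3y at -0.72. With the replicate block Pf4 was at -0.99 and Ddx3y at -3.79. With the surrogate variable Cdk1 was at -0.17 and Ddx3y at -0.19. With the sex index Pf4 was at -0.0577, Xist at -1.39, Ddx3y at -1.34 and the stalk list at 0.00419. Without heterozygous 1 and knockout 2, Cdk1 was at -0.26, Col3a1 at 0.0384, oxidative phosphorylation at -0.0101 and choroid plexus at -1.49. Without heterozygous 2 and knockout 1, Foxc1 was at 0.0538 and the stalk, fenestration, mitosis and immediate-early lists at -0.0657, -0.18, 0.12 and -0.15. With the neuronal score Cdk1 was at -0.51, Ccnb1 at -0.0921, Col3a1 at 0.86, Olig1 at 0.38, Ddx3y at -0.95 and the oxidative phosphorylation, fibroblast and choroid plexus lists at -0.0783, 0.74 and -1.74, and the mitochondrial synthetase list at -0.0237. With the other-cell score Stmn2 was at 0.92, Cavin3 at -0.18, Cdk1 at -0.91, Ccnb1 at -0.55, Tgfb1 at -0.00143, Atp5a1 at -0.0343, Dcx at 0.36, Neurod2 at 0.72, Elavl3 at 0.60, Tubb3 at 1.06, Slc1a3 at 0.11, Lhx2 at 0.87, Col3a1 at 2.72, Cspg5 at 0.60, Olig1 at 0.83 and Ddx3y at -4.77. In the same setting the lists of identity, TGF-beta, leukocyte adhesion and oxidative phosphorylation were at 0.12, 0.0362, -0.45 and -0.0748, and those of neurons, radial glia, microglia, fibroblasts, choroid plexus and oligodendrocyte precursors at 1.81, 1.90, 0.29, 2.67, -2.15 and 0.82; the score is built from the first 3 of the latter. The cytosolic and mitochondrial synthetase lists were then at 0.0375 and -0.21. Over the fits that left out 1 library, the ranges were -0.17 to 0.24 for Cdk1, -0.17 to 0.0542 for Foxc1, -1.49 to 0.69 for Pf4, -2.78 to 1.79 for Ttr, -0.0709 to 1.04 for Xist and -6.83 to 2.996 for Ddx3y. For lists they were -0.22 to 0.10 for stalk, -0.35 to -0.12 for fenestration, -0.11 to 0.29 for immediate-early, -1.24 to 0.79 for platelets, -2.44 to 0.36 for choroid plexus, -0.21 to 0.13 for mitosis and -0.0228 to 0.17 for oxidative phosphorylation. Without 1 library the TGF-beta and oxidative phosphorylation lists (without heterozygous 4), the VEGF list (without knockout 2) and the mitosis and oxidative phosphorylation lists (without knockout 4) newly passed camera. So did the mitosis and interferon lists with the neuronal score, and the mitosis, fenestration and platelet lists with the other-cell score, where the chaperone list lost its call (adjusted p = 0.327). List medians also changed sign 32 times while camera's direction stayed, 13 of them without 1 library. The mitochondrial synthetase list was at -0.0311 with upper-quartile factors and -0.0813 with library size alone, where identity was at -0.0385 and oxidative phosphorylation at -0.0424. The stalk list was at 0.0208 with no filter, 0.0628 with the replicate block, 0.0285 with the neuronal and 0.0260 with the other-cell score. The X-inactivation and Y-linked list was at -0.49, -3.79, -0.95 and -4.77 in these 4 settings, at -1.39 with the sex index and at -0.21 without heterozygous 1 and knockout 2. Platelets were at -0.69 with the replicate block, heme at 0.00527 without heterozygous 2 and knockout 1, choline at -0.0442 and radial glia at 0.12 with the neuronal score, and pericytes at 0.24 with the other-cell score. Without 1 library the medians of identity, the X-inactivation and Y-linked list, mitochondrial synthetases, NRF2 and heme ranged from -0.0190 to 0.24, -6.83 to 1.62, -0.0330 to 0.11, -0.28 to 0.00302 and -0.16 to 0.0112. Of the remaining values over all settings, 2113 for genes and 733 for lists kept direction (for lists camera's) and side of the threshold, 614 and 69 fell short of it, and 12 and 20 newly passed.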

Other observations

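Every gene list and test in this part was chosen after the results were seen, and the tests with a score in the model were first run on called members and then on all tested members. Genes of the secretory pathway were higher in knockout, with 23 of 44 rising and 0 falling (29 adjusted over the list alone; median log2 fold change 0.65; camera adjusted p = 2.60e-16; adjusted p = 0.0386 with an estimated correlation). Kdelr2, a receptor gene that returns proteins to the endoplasmic reticulum, rose 2.61-fold from 148 ± 22.2 to 387 ± 40.9 CPM. Sec24d, a coat gene of transport vesicles, rose 3.82-fold, and Rpn1 and Sec61a1, genes of the glycosylation and translocation machinery, 2.03-fold and 2.05-fold. Of 6 tested GIMAP genes, a family of immune GTPases, Gimap4, Gimap6 and Gimap9 rose 3.76-fold, 2.10-fold and 1.77-fold and 0 fell (3 adjusted over the list alone; camera adjusted p = 0.00196; adjusted p = 0.152 with an estimated correlation). In the same libraries the list means of neurons, pericytes and microglia differed by -2.28, -2.08 and -1.37. The secretory call held in all 8 fits that left out 1 library (median 0.61 to 0.72), with the neuronal score (0.51) and with the other-cell score (0.55). The GIMAP call held in all 8 of those fits but was lost with the neuronal score (median 0.32) and with the other-cell score (0.17), where camera adjusted p was 0.0531 and 0.950. The hypothesis that the secretory set rose beyond the endothelial identity set could not be decided: its excess was 0.45 (95% interval 0.12 to 0.78), with an exact permutation p of 0.0571.

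Of 20 cytosolic transfer RNA synthetase genes 6 rose and 0 fell (11 adjusted over the list alone; camera adjusted p = 8.11e-04; adjusted p = 0.346 with an estimated correlation), among them Rars (1.90-fold), Tars (1.75-fold) and Nars (1.95-fold). With library size alone as the scaling 3 of these genes rose, and with the replicate number as a block 0. Of 17 mitochondrial synthetase genes Mars2 rose 1.81-fold (1 adjusted over the list alone; camera adjusted p = 0.281). The cytosolic mean exceeded the mitochondrial mean by 0.36 more in knockout (95% interval 0.05 to 0.68; exact permutation test, p = 0.0286, the smallest this design allows), so a larger rise of the cytosolic than of the mitochondrial set is consistent with these data. The cytosolic camera call held in all 8 fits that left out 1 library and with the neuronal score (median 0.54; adjusted p = 0.0230), and was lost with the other-cell score, where camera's direction turned (median 0.0375; adjusted p = 0.988). The neuron list mean differed by -2.28 between the same libraries. Cars is also in the ATF4 list.

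Among the 35 splits of the 8 libraries into 4 and 4, the real one gave 1293 called genes and the highest other split gave 0. This share, 1 of 35, is the smallest the design allows, so it argues against chance as the source without excluding it. Every other split mixes the genotypes within its groups, so any real difference between them also lowers its count. Nor can the splits tell genotype from a sort or batch shared by the libraries of a group. The same held for the 749 higher genes (1 of 35 splits, highest other 0) and the 544 lower genes (1 of 35 splits, highest other 0). For the number of endothelial lists that passed camera, chance was not excluded: 8 of 35 splits gave at least the real 12, and the highest other gave 16.

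Tip cell, ATF4 and p53 target genes were higher in knockout, and technical sources could in part account for this. Dilution of endothelial RNA in heterozygous libraries is argued against, since each list rose beyond the identity list, the p53 targets least, by 0.91 (95% interval 0.37 to 1.46). RNA of neural cells is argued against as the whole cause, since the genotype term over all 66 members was 1.49 with the neuronal score in the model (95% interval 0.58 to 2.39) and 1.46 without it. With the other-cell score it was 1.30 (95% interval -0.12 to 2.72), with an SE of 0.552 against 0.221 with neither score. Handling stress cannot be told apart from genotype, since immediate-early and heat-shock genes differed by -0.0430 (95% interval -0.70 to 0.61; exact permutation test, p = 0.857), and an effect of genotype stays open and untested.

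Cholesterol genes were lower in knockout, and loss of RNA from other cells could account for part of this. Over all 23 members the genotype term was -0.90 alone (95% interval -1.09 to -0.71) and -0.74 with the neuronal score in the model (95% interval -0.94 to -0.54). With the other-cell score it was -0.63 (95% interval -1.01 to -0.25). Loss of neural RNA is therefore argued against as the whole cause. For the cell types scored together this cannot be decided, since the other-cell score closely tracks genotype (variance inflation 5.31). The interval with that score also ended near the limit of -0.25, which was set after the results were seen. An effect of genotype stays open and untested.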
